A study of Mus musculus with 6 samples.

How the data were processed

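Libraries were made from total RNA of CD4+ FOXP3-GFP+ cells sorted from mouse bone marrow, extracted with the RNeasy Micro kit and prepared with the NEBNext Ultra RNA kit, per the labels' protocols. This kit does not mark strand, so reads from overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name Picard, STAR, RSEM and DESeq2 and the mouse build mm10. Versions and settings are not given in the sources used here.

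Each of the 6 deposited tables is an RSEM gene table with 47643 genes, and replicates were not pooled. The authors' expected counts are RSEM's estimates of reads per gene, not normalized and not always whole, per the file headers. The deposited tables also hold TPM and FPKM, both scaled by the authors' RSEM run for library total and effective length, per the file headers. TPM and FPKM entered no test. The authors' transcript and effective lengths are in the same deposited tables, and effective length served in 1 alternative only. RSEM divides reads that fit several genes by a model, so counts of close paralogs such as the Ifit, Oas, Gbp, Tgtp, Ifi200 and class I families, and of the alpha-globin copies, are uncertain.

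Gene identifiers in the tables are versioned Ensembl IDs. Without the version, 47224 of 47643 matched the reference names, and 419 kept the name in the tables. Positions are those of GENCODE release M21 on GRCm38, the assembly that mm10 denotes, counted from 1. Transcript length and GC content are those of the longest transcript per gene and were known for 99.7% of the genes tested.

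Groups came from the labels, 3 myeloma and 3 control libraries. The series design speaks of 3 mice per group. Beyond that, nothing ties a replicate number to a mouse or day, so p-values measure the spread between these libraries. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), scaled by TMM, and tested with glmQLFit and glmQLFTest in edgeR 4.0.16 (R 4.3.3), myeloma minus control, with Benjamini-Hochberg adjustment over the 13235 genes tested and a threshold of 0.05. Adjusted p-values of single genes come from this test unless another is named. The SE of a log2 fold change is its size divided by the square root of its F statistic. The SE of a list's median is a bootstrap over the list's genes, which are not independent, and does not measure the spread between libraries. CPM values use the TMM-scaled library sizes. The biological coefficient of variation was 0.202. Total expected counts were 12008165, 10240620 and 11777901 in myeloma replicates 3, 4 and 5 and 12315318, 11688282 and 13314631 in control replicates 1, 3 and 5. A two-sided exact permutation test of 3 against 3 values cannot give p under 0.1, so summed marker levels are given per library with no test.

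The lists of genes, the rule for naming genes and all other settings but 1 were fixed before the data were examined. There were 37 lists: 23 gene groups and 14 lists of cell type markers. Of these, 35 had at least 5 genes tested and were tested with limma's camera (3.58.1) at a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation. The fry test asks whether a list's genes move, on balance, one way and does not compare them with other genes. With the preset correlation 23 lists were called, with the estimated correlation none, and fry called 10 of the 23. Lists share genes, so their counts are not independent. Members held by another list were 8 of 16 cytotoxic granule genes, 12 of 32 effector and 11 of 30 identity genes. They were also 11 of 31 interferon gamma and 8 of 19 class I genes.

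Per direction, the rule for naming genes considers called genes whose groups do not overlap, without predicted models, pseudogenes or antigen receptor genes. From these it takes the 10 largest fold changes with a mean of at least 5 CPM and the 5 smallest p-values. It adds up to 4 members with the smallest p from each list and a fixed set of regulatory T cell and interferon receptor genes. Exceptions are said to be so where they occur.

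The other settings were RLE and upper-quartile factors, library sizes alone, no filter, at least 1 CPM in 3 samples, an effective-length offset, DESeq2 1.42.0, limma-voom, robust dispersion, removal of immunoglobulin, haemoglobin and mitochondrial genes, the replicate number as a block, and leaving out each library. With the replicate number as a block the group contrast rests on numbers 3 and 5, since myeloma replicate 4 and control replicate 1 stand alone. A correction for transcript length and GC content (splines with 4 degrees of freedom per library, used as offsets) was added after the data were examined. Principal components used log2 CPM with a prior count of 2. The main test was tested on simulated data for the 13235 genes, where it recovered 20.9% of genes changed 1.5-fold, 53.7% of genes changed 2-fold and 86.4% of genes changed 4-fold, with 3 false calls among 110. Intervals for shares of reads are exact binomial at 95% and cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.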

Results

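RNA was sequenced from regulatory T cells, sorted by flow cytometry as CD4+ cells carrying the GFP reporter of FOXP3, from the bone marrow of mice. FOXP3 is the transcription factor that defines this suppressive T cell lineage. Marrow came from 3 mice injected with Vk*MYC myeloma cells, a transplantable mouse model of the plasma cell cancer multiple myeloma, and from 3 control mice. The myeloma libraries carry replicate numbers 3, 4 and 5 and the control libraries 1, 3 and 5. Total expected counts per library ran from 10240620 in myeloma replicate 4 to 13314631 in control replicate 5. Of 47643 annotated genes, 13235 had enough counts to be tested. The series title names the type I interferon receptor subunit IFNAR1, so the comparison asks which transcripts, and in particular which interferon-response transcripts, differ between regulatory T cells of myeloma-bearing and control marrow.

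In regulatory T cells from myeloma-bearing marrow, 62 of 63 genes of the type I interferon response were higher by edgeR's quasi-likelihood test. Isg15, which encodes a ubiquitin-like interferon-induced protein, reached 141 ± 21.2 CPM (SD, n = 3) against 12.0 ± 2.52 CPM in controls (n = 3). Gzmb, the cytotoxic protease granzyme B, reached 154 ± 26.1 CPM against 20.7 ± 1.75. Of 23 genes of resting, recirculating T cells 12 were lower, among them Tcf7, a transcription factor of naive and memory T cells, at 243 ± 19.9 against 470 ± 18.7 CPM. Foxp3 itself, at 1020 ± 42.0 against 1134 ± 130 CPM, did not pass the test (log2 fold change -0.15, SE 0.11, adjusted p = 0.385).

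By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 838 genes were higher and 621 lower in myeloma at the threshold of 0.05. Of these, 262 were higher and 83 lower by more than 2-fold. The 3 myeloma and 3 control values did not overlap for 1455 of the 1459 genes called. Among all genes tested, 33.3% were separated in this way, where chance gives 10%. The counts were lower whichever library was left out. They were 452 higher and 207 lower without myeloma replicate 3, 394 and 177 without myeloma replicate 4, 331 and 123 without control replicate 3, and 445 and 265 without control replicate 5. Without myeloma replicate 5 they were 836 and 546, and without control replicate 1 they were 644 and 523. These fits have fewer samples, so a drop does not by itself show that the counts rest on the library left out. With library sizes alone in place of scaling factors, the split was 633 higher and 1004 lower.

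For fold changes the naming rule leaves out genes with a mean under 5 CPM and antigen receptor genes such as Ighg2b (log2 fold change 8.25). Among the genes it admits, the 10 largest increases were led by Jchain (log2 fold change 5.44, SE 0.68), the joining chain of secreted immunoglobulin and a plasma cell product. It was followed by the interferon-inducible Ifi44 at 4.34 (SE 0.29) and by Nanp, a sialic acid phosphatase, at 4.06 (SE 1.12). The rest were all interferon-inducible: Ifi204 at 4.05, Ifit3b at 3.89, Ifi211 and Mx1 at 3.78, the chemokine Cxcl10 at 3.75, and Oas2 and Ifit3 at 3.70. Nanp passed in only 1 of the 6 fits that left out 1 library, the one without control replicate 3, and its adjusted p reached 0.178 without myeloma replicate 4. It was 0.0702 without myeloma replicate 3, 0.0523 without myeloma replicate 5, 0.0861 without control replicate 1 and 0.121 without control replicate 5. It also lost its call with DESeq2 (0.224), limma-voom (0.051), robust dispersion (0.149), the effective-length offset (0.0698) and the length and GC correction (0.0757). Jchain lost its call with limma-voom (0.0797). The smallest p-values among higher genes belonged to Gbp10, an interferon-induced GTPase (log2 fold change 2.26, SE 0.08, adjusted p = 4.45e-06), Bst2, Gzmb, Ifi27l2a and Isg15.

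Of the 63 measured genes of the type I interferon response 62 rose and none fell, and adjusted over the list alone 62 were higher and 1 lower. The median log2 fold change was 1.55. Bst2, the membrane protein tetherin (8:71534255-71537456 in mm10), rose 5.21-fold (log2 fold change 2.38, SE 0.11, adjusted p = 1.54e-05). Ifi27l2a rose 4.33-fold, from 166 ± 9.30 to 718 ± 70.7 CPM. Isg15 (ENSMUSG00000035692.6, 4:156199424-156200818) rose 11.7-fold and the exonuclease gene Isg20 rose 4.05-fold. The single member not called was Ly6c1, at a log2 fold change of -0.46 (SE 0.13, adjusted p = 0.0606), named here after its value was seen. It passed as lower without myeloma replicate 4 (0.0467) and with upper-quartile factors (0.0497), library sizes alone (0.0374), no filter (0.00379), DESeq2 (0.0287) and the length and GC correction (0.0161). The list test gave adjusted p = 6.3e-176 with the preset correlation and adjusted p = 0.0673 with an estimated correlation. Between 56 and 60 members were higher whichever library was left out. Members of the Ifit, Oas, Mx and Ifi200 families share sequence with close relatives, so the split of reads among them is uncertain. Plasma cell markers were also higher in the same 3 libraries, with summed levels of 650 CPM in myeloma replicate 3, 1713 in replicate 4 and 3254 in replicate 5, against 355 to 372 CPM in controls.

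**Figure D1:**
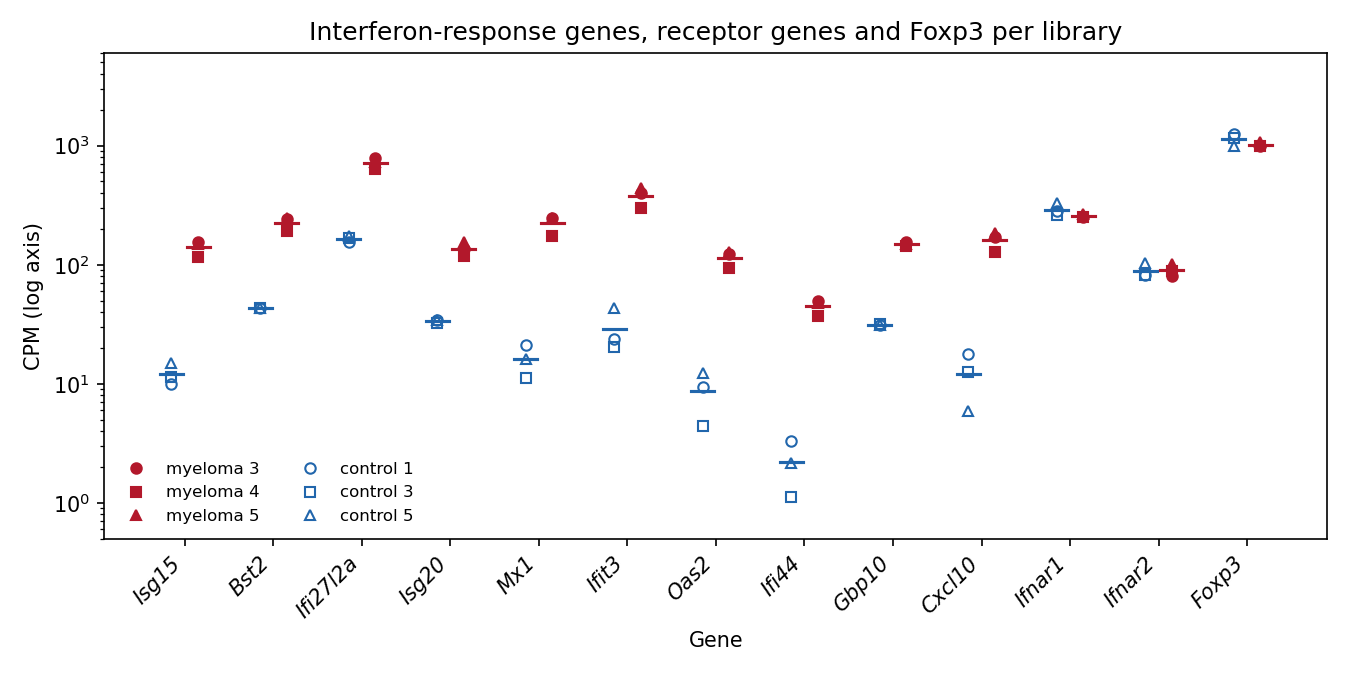
CPM per library on a log axis for 10 interferon-response genes, the receptor genes Ifnar1 and Ifnar2, and Foxp3, with filled points for the 3 myeloma libraries, open points for the 3 control libraries and a line at each group's mean. The myeloma and control points of Isg15 lie around 141 and 12.0 CPM, while those of Ifnar2 lie around 90.2 and 88.7 CPM.

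Genes that respond preferentially to interferon gamma had 22 of 31 measured members higher, none lower and 25 higher adjusted over the list alone. Gbp10, the GTPase genes Tgtp2 (log2 fold change 1.49, SE 0.08) and Gbp6 (1.41, SE 0.09), and Irgm1 (1.61, SE 0.11) rose, and the median of the list was 0.90. Its adjusted p was 1.82e-41, and adjusted p = 0.0673 with an estimated correlation. Of 19 genes for class I antigen presentation, 14 rose and none fell (16 higher adjusted over the list alone, median 0.59). They included the class I heavy chain H2-T22 at 2.01-fold, the proteasome activator Psme2 at 1.89-fold, and the immunoproteasome subunits Psmb8 at 1.75-fold and Psmb9 at 2.07-fold. The list gave adjusted p = 1.57e-19, and adjusted p = 0.17 with an estimated correlation. Gbp, Tgtp and class I genes belong to families of similar sequence, and their counts are uncertain to that extent. The counts were lowest at 17 of the interferon gamma genes without myeloma replicate 3 and at 9 of the class I genes without myeloma replicate 3 or control replicate 5.

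The receptor genes differed by less than the test could call. Ifnar1 (ENSMUSG00000022967.12, 16:91485238-91507441), whose product the series title names, was at 257 ± 9.04 CPM in myeloma and 291 ± 35.6 in controls (log2 fold change -0.18, SE 0.10, adjusted p = 0.284). Ifnar2 was at 90.2 ± 10.5 and 88.7 ± 12.2 CPM (0.02, SE 0.12, adjusted p = 0.924), and its sign turned without myeloma replicate 5 (-0.07), control replicate 1 (-0.04) or control replicate 3 (-0.04). Of 14 genes for interferon receptors and signalling, Jak2 (log2 fold change 0.43) and Socs3 (0.38) rose and Jak1 (-0.40) fell, and adjusted over the list alone 6 were higher and 2 lower. The list as a whole was not called (adjusted p = 0.344). Jak2 lost its call without myeloma replicate 3 (0.0632), control replicate 3 (0.0594) or control replicate 5 (0.0568). Socs3 lost its call without myeloma replicate 3 (0.079), control replicate 1 (0.0567) or control replicate 3 (0.0911), and with the length and GC correction (0.138) or the effective-length offset (0.0554). Jak1 lost its call in all 6 fits that left out 1 library, with adjusted p from 0.0593 without myeloma replicate 5 to 0.127 without control replicate 5, and also with the length and GC correction (0.132) and the effective-length offset (0.0504).

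Il2ra, the high-affinity interleukin-2 receptor chain (log2 fold change -0.24, SE 0.09, adjusted p = 0.131), Ctla4, an inhibitory receptor (-0.25, SE 0.25, adjusted p = 0.56), and Ikzf2, which encodes Helios (0.05, SE 0.12, adjusted p = 0.828), were not called, nor were Icos (0.24), Cd4 (-0.08) and Cd3e (0.04). In the list of regulatory T cell identity genes, 9 of 30 rose and 3 fell, with 10 higher and 3 lower adjusted over the list alone and a median of 0.13. Those that rose included Gzmb, Klrg1, the receptor gene Tnfrsf4 (log2 fold change 0.98, SE 0.15, adjusted p = 0.00532) and Capg (0.69, SE 0.11). Tnfrsf18, which encodes the costimulatory receptor GITR, also rose (0.69, SE 0.11, adjusted p = 0.00776). The 3 that fell were Nrp1 (-0.56), Lrrc32 (-0.98) and Gpr83 (-0.68), named here after their values were seen. Lrrc32 lost its call without myeloma replicate 3 (0.116), myeloma replicate 4 (0.148), control replicate 1 (0.0829) or control replicate 3 (0.146), and Gpr83 without myeloma replicate 3 (0.107), control replicate 1 (0.0585), control replicate 3 (0.146) or control replicate 5 (0.135). With the length and GC correction Gpr83 (0.087) and Tnfrsf18 (0.0505) lost theirs, and with robust dispersion (0.138, 0.0525) or the effective-length offset (0.0525, 0.0647) Lrrc32 and Gpr83 did. The list test gave adjusted p = 0.000485, and adjusted p = 0.426 with an estimated correlation. Only 1 member was lower without myeloma replicate 3, control replicate 1 or control replicate 3, and the number higher went down to 6 without myeloma replicate 4. The median was 0.04 without control replicate 5.

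Among 32 effector and inhibitory-receptor genes of regulatory T cells, 11 rose and none fell, with 15 higher and 1 lower adjusted over the list alone and a median log2 fold change of 0.66. Gzmb (ENSMUSG00000015437.4, 14:56258838-56262260) rose 7.41-fold (log2 fold change 2.89, SE 0.14, adjusted p = 1.54e-05). Fgl2, a secreted suppressive mediator, rose 2.95-fold, Klrg1, a marker of terminally differentiated lymphocytes, 2.38-fold, and the transcription factor Batf 1.78-fold. By edgeR's test these inhibitory receptors did not pass, with Lag3 at a log2 fold change of 1.56 (SE 0.55, adjusted p = 0.102), Pdcd1 at 0.99 (SE 0.28, adjusted p = 0.0554) and Tigit at 0.68 (SE 0.29, adjusted p = 0.167), and neither did the cytokine Il10 at 1.20 (SE 0.58, adjusted p = 0.215). Control replicate 1 lay near the myeloma libraries for these receptors. Without it Lag3 (0.000734), Pdcd1 (0.00478) and Tigit (0.00235) passed, and Pdcd1 also passed without myeloma replicate 5 (0.0369). With limma-voom on all 6 libraries Lag3 (log2 fold change 1.98, adjusted p = 0.0309) and Pdcd1 (1.05, adjusted p = 0.0377) passed. With no low-count filter Lag3 (7.58e-28), Pdcd1 (1.66e-17), Tigit (3.16e-08) and Il10 (3.8e-10) did. In control replicate 1 the Lag3 level was 44.9 CPM, against 8.59 and 9.29 in the other controls and 44.8 to 74.1 in myeloma. The Tigit level of that library was 166 CPM, against 84.3 and 62.7 in the other controls and 165.2 to 168.7 in myeloma. Its Pdcd1 level was 111.6 CPM, against 109.9 to 174.5 in myeloma. Since the groups overlapped for Lag3, Tigit and Pdcd1, p-values this small without a filter do not reflect the spread between libraries. Neither they nor the Il10 value of that fit are taken as evidence of a difference. The same limit holds for the other calls quoted from the fit with no filter. The list gave adjusted p = 1.64e-09, and adjusted p = 0.366 with an estimated correlation. The number of members higher was 16 without control replicate 1, 7 without myeloma replicate 3 or control replicate 5, and 6 without myeloma replicate 4 or control replicate 3.

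Of 16 cytotoxic granule genes, 8 rose and none fell (11 higher adjusted over the list alone, median 0.82). Another list also holds 8 of the 16, among them Gzmb and Klrg1, which were counted in the lists above. Ccl5, a chemokine of activated T cells, rose 4.55-fold (log2 fold change 2.18, SE 0.20), and the death ligand Tnfsf10 rose 1.57-fold. Camera gave adjusted p = 6.5e-13, and adjusted p = 0.17 with an estimated correlation. Tbx21, the transcription factor T-bet of type 1 helper cells, rose 3.99-fold (log2 fold change 1.99, SE 0.28, adjusted p = 0.00416), and Il12rb1 rose 1.94-fold. With Tnf (log2 fold change 1.03) they were the 3 of 15 helper lineage genes that rose (4 adjusted over the list alone). That list gave adjusted p = 0.0233, and adjusted p = 0.277 with an estimated correlation. The helper list lost its call without myeloma replicate 3 (0.0612), myeloma replicate 4 (0.0537) or control replicate 5 (0.054). Tnf lost its call without myeloma replicate 4 (0.0529) or control replicate 3 (0.0603). NK cell markers in the same libraries summed to 38.6, 45.9 and 140 CPM in myeloma replicates 3, 4 and 5 and to 17.3 to 24.9 CPM in controls.

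Of 23 genes of resting and recirculating T cells 12 fell and 1 rose (16 lower and 1 higher adjusted over the list alone), with a median of -0.54. Tcf7 (ENSMUSG00000000782.15, 11:52252371-52283014) had a log2 fold change of -0.95 (SE 0.09, adjusted p = 0.000423). S1pr1, the receptor that guides lymphocytes out of tissue, stood at -0.83 (SE 0.08), the complement regulator Cd55 at -1.03 (SE 0.10) and the chromatin organiser Satb1 at -0.82 (SE 0.11). The member that rose was Ly6c2 (2.77, SE 0.39), which also belongs to the type I interferon list and was named here after its value was seen. The list gave adjusted p = 3.15e-14, and adjusted p = 0.17 with an estimated correlation. Tcf7, S1pr1 and Cd55, with Ift80 (-0.77) and Med13l (-0.59), had the 5 smallest p-values among lower genes.

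The 10 largest decreases were taken among genes with a mean of at least 5 CPM. Below that mean, the B cell markers Cr2 (log2 fold change -4.47) and Fcer2a (-3.86) were also called lower. The 10 were Scd1, a fatty acid desaturase (log2 fold change -3.95, SE 0.71), the kinase gene Plk2 (-3.39), Fosb (-3.12), the B cell transcription factor gene Pax5 (-3.04), Fcmr, the IgM receptor (-2.59), H2-DMb2 (-2.57), Ppp1r15a (-2.34), Klf4 (-2.25), Rgs2 (-2.23) and Tnfaip3, an inhibitor of NF-kB (-2.21). Ppp1r15a and Rgs2 passed whichever library was left out. Tnfaip3 lost its call without myeloma replicate 4 (adjusted p = 0.0575), and Scd1 without myeloma replicate 3 (0.0513) or 4 (0.0619). Without myeloma replicate 3, myeloma replicate 4 or control replicate 3, the calls of Plk2 (0.0627, 0.106, 0.12), Fosb (0.0733, 0.0847, 0.0597), Pax5 (0.0754, 0.105, 0.091), Fcmr (0.0798, 0.0888, 0.0821), H2-DMb2 (0.101, 0.143, 0.128) and Klf4 (0.134, 0.149, 0.197) were lost. All of these except Fosb also lost it without control replicate 5, at 0.0514, 0.0932, 0.0881, 0.153 and 0.068, and Klf4 without control replicate 1 (0.0553). With limma-voom Scd1 (0.202), Plk2 (0.0635), Pax5 (0.151), Fcmr (0.175), H2-DMb2 (0.114) and Klf4 (0.0831) lost their calls. With robust dispersion Scd1 (0.0586), Plk2 (0.138), Fosb (0.123), Pax5 (0.119), H2-DMb2 (0.0768), Ppp1r15a (0.0514), Klf4 (0.146) and Tnfaip3 (0.0718) lost theirs, as did Fcmr (0.148) and Klf4 (0.0895) with the effective-length offset and Klf4 (0.054) with the length and GC correction. Summed B cell markers were 99.5 CPM in control replicate 1 against 360 and 415 CPM in the other controls and 70.8 to 159 CPM in myeloma.

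Of 23 immediate early and heat shock genes, which respond within minutes to stimulation and to cell handling, 10 fell and 1 rose, with 11 lower and 1 higher adjusted over the list alone and a median of -0.51. Fos fell by 2.19 on the log2 scale (SE 0.39), Btg2 had a log2 fold change of -1.18 (SE 0.17) and Zfp36 of -1.12 (SE 0.18). Hspe1 was the member that rose (0.46). The adjusted p of the list was 7.91e-07, and adjusted p = 0.37 with an estimated correlation. Levels varied among controls, with Fosb at 107, 315 and 70.3 CPM in control replicates 1, 3 and 5. Members lower numbered 3 without myeloma replicate 3, 4 without myeloma replicate 4 and 6 without control replicate 3, where the median was -0.25, and 4 with robust dispersion. Fos lost its call without myeloma replicate 3 (adjusted p = 0.0503) and with robust dispersion (0.084). Hspe1 lost its call with the length and GC correction (0.358), the effective-length offset (0.0621) and library sizes alone (0.0659). Hspe1 lost it without myeloma replicate 3 (0.12), myeloma replicate 4 (0.138), control replicate 1 (0.106), control replicate 3 (0.0544) or control replicate 5 (0.147).

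Of 40 nuclear genes of oxidative phosphorylation 28 rose and none fell (33 higher adjusted over the list alone, median 0.52). The cytochrome c oxidase subunits Cox5a, Cox5b and Cox6b1 rose 2.01-fold, 1.71-fold and 1.44-fold. This list gave adjusted p = 1.61e-16, and adjusted p = 0.261 with an estimated correlation. All 13 mitochondrially encoded genes had positive fold changes (median 1.12), and mt-Nd3, mt-Co3 and mt-Co2 were called, with 10 higher adjusted over the list alone. This list gave adjusted p = 8.18e-05, and adjusted p = 0.452 with an estimated correlation. Mitochondrial transcripts took 8.24% of expected counts in myeloma replicate 5, 2.83% and 3.34% in myeloma replicates 3 and 4, and 2.21% to 2.50% in controls. Without myeloma replicate 5 the median of the mitochondrial list was 0.45. mt-Nd3 lost its call without control replicate 5 (0.0533) and with robust dispersion (0.0783), as did mt-Co3 (0.0569) and mt-Co2 (0.113), and mt-Co2 also with the effective-length offset (0.0558). Without myeloma replicate 4, control replicate 1, control replicate 3 or control replicate 5, mt-Co3 (0.101, 0.0682, 0.104, 0.0936) and mt-Co2 (0.083, 0.0953, 0.114, 0.124) lost theirs. Of 67 cytosolic ribosomal protein genes, Rpl41, Rps2 and Rpl13 rose (3 higher adjusted over the list alone, median 0.26). Rpl13 lost its call without myeloma replicate 3 (0.0616), myeloma replicate 4 (0.0782), control replicate 1 (0.0553) or control replicate 3 (0.0877). The ribosomal list gave adjusted p = 1.7e-06, and adjusted p = 0.567 with an estimated correlation.

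Across all genes, the median log2 fold change went from 0.30 among genes with the shortest transcripts to -0.18 among those with the longest. A correction for transcript length and GC content, added after the data were examined, left 453 genes higher and 299 lower, 61 members of the type I interferon list higher, and 12 resting T cell genes lower. In all 39 of the genes tabulated one by one lost their calls under it. Under it 6 oxidative phosphorylation genes stayed past the threshold (median 0.28), and the ribosomal list was not called (median 0.05, adjusted p = 0.392). The mitochondrial list kept a median of 0.90 (adjusted p = 0.000789), with 1 gene called. Tnfrsf18 (log2 fold change 0.47, adjusted p = 0.0505), Cox6b1 (0.27, 0.105), mt-Co2 (0.86, 0.15), mt-Co3 (0.70, 0.139), Rpl41 (0.33, 0.0928), Rps2 (0.27, 0.12) and Rpl13 (0.48, 0.0852) also lost their calls. Leaving out 1 library brought the oxidative phosphorylation genes called to 9 without myeloma replicate 3 or 4, 11 without control replicate 3 or 5, and 17 without control replicate 1, and taking the replicate number as a block brought them to 2. The mitochondrial genes called numbered 6 without myeloma replicate 5, 1 without myeloma replicate 4, control replicate 1 or control replicate 3, and 0 without control replicate 5. The mitochondrial genes called numbered 13 with no filter and 0 with robust dispersion or the replicate number as a block. The ribosomal genes called numbered 25 without myeloma replicate 5, 20 with DESeq2, 13 with no filter, 6 with limma-voom, 5 with robust dispersion and 1 with the replicate number as a block. Both counts with no filter come from the fit whose p-values for Lag3, Tigit and Pdcd1 did not reflect the spread between libraries.

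**Figure D2:**
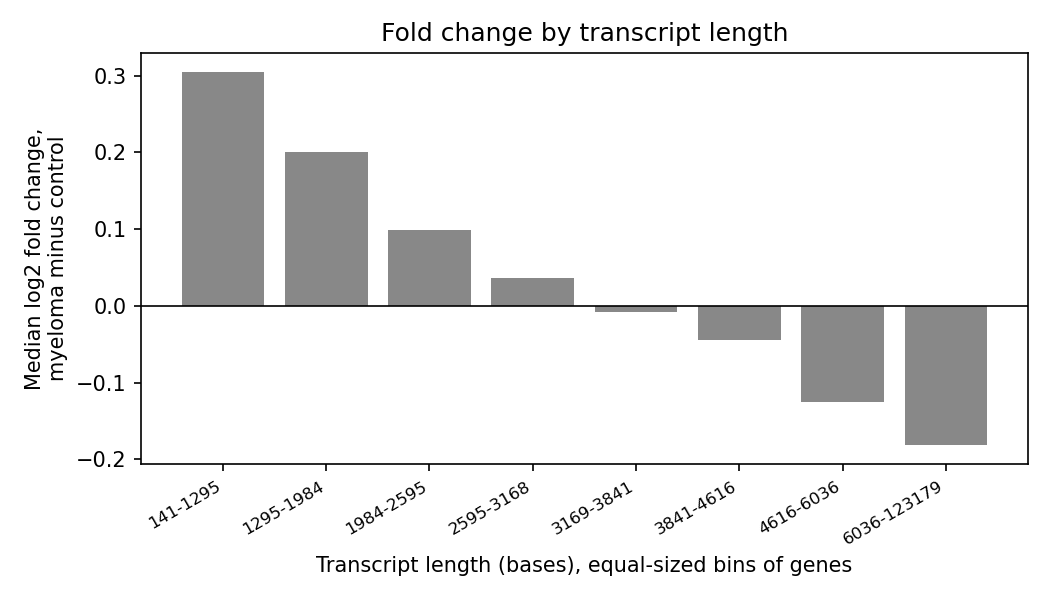
Median log2 fold change (myeloma minus control) in 8 equal-sized bins of genes ordered by transcript length in bases. The medians run from 0.30 in the bin of shortest transcripts to -0.18 in the bin of longest.

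Of 23 cholesterol synthesis genes 9 rose and none fell (12 higher adjusted over the list alone, median 0.43), including the sterol demethylase Cyp51 (log2 fold change 1.28, SE 0.13) and the synthase gene Fdps (1.08, SE 0.14). The cholesterol list gave adjusted p = 4.77e-05, and adjusted p = 0.237 with an estimated correlation. The number higher was 3 without myeloma replicate 3 or 4, 4 without control replicate 3, and 5 without control replicate 1 or 5. In the unfolded protein response list, 5 of 22 rose and Dnajb9 (-1.65, SE 0.25) fell (9 and 1 adjusted over the list alone, median 0.27). Manf, a secreted protein of the stressed endoplasmic reticulum, rose 1.70-fold, Pdia3 1.32-fold and Sdf2l1 2.22-fold, and the others that rose were Ddit3 (0.78) and Pdia6 (0.46), chosen after their values were seen. Sdf2l1 lost its call without myeloma replicate 4 (0.0619) or control replicate 3 (0.0753), Pdia3 without myeloma replicate 3 (0.054), myeloma replicate 4 (0.0522) or control replicate 3 (0.076), Pdia6 without myeloma replicate 4 (0.129), myeloma replicate 5 (0.0857), control replicate 3 (0.154) or control replicate 5 (0.134), and Ddit3 without any library but myeloma replicate 5, up to 0.0899 without myeloma replicate 4. With the length and GC correction Sdf2l1 (0.0623), Ddit3 (0.123) and Pdia6 (0.131) lost theirs, and Pdia6 also with the effective-length offset (0.161) and library sizes alone (0.0725). Only 1 member was higher without myeloma replicate 4 or control replicate 3, and 3 were without control replicate 5. Plasma cells, whose markers summed to 650, 1713 and 3254 CPM in myeloma replicates 3, 4 and 5 and to 355 to 372 CPM in controls, also express genes of this list. That list gave adjusted p = 0.0153, and adjusted p = 0.452 with an estimated correlation, and it lost its call without myeloma replicate 4 (0.0538), with the length and GC correction (0.0589), with the effective-length offset (0.124) and with the replicate number as a block (0.0892).

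The remaining lists of T cell programmes were not called as groups. In the 24 chemokine receptor and homing genes, 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0832). Cxcr3, a receptor for Cxcl10, rose 2.08-fold, and the integrin genes Itga1 (log2 fold change 2.20) and Itga4 (-0.51) were also called. Cxcr3 lost its call without control replicate 3 (0.0552), Itga4 without myeloma replicate 3 (0.06), myeloma replicate 4 (0.0748) or control replicate 3 (0.0798), and Itga1 whichever library was left out, from 0.0589 without myeloma replicate 3 to 0.164 without control replicate 5. Itga4 also lost its call with the length and GC correction (0.0867), and Itga1 with limma-voom (0.0834), the effective-length offset (0.0636) and no filter (0.073). This list passed without control replicate 1 (0.00565), with no filter (0.0135) and with the replicate number as a block (0.0195). In T cell receptor early response and NF-kB genes, 6 of 29 rose and 3 fell, with 8 and 5 adjusted over the list alone (adjusted p = 0.306). Relb (log2 fold change 0.64) and Nr4a3 (1.36) were among the higher genes, and Tnfaip3, Spry1 (-0.87) and Nfkbiz (-0.80) were the lower, the last 2 chosen after their values were seen. Tnfaip3 lost its call without myeloma replicate 4 (0.0575), Spry1 without myeloma replicate 3 (0.0571), myeloma replicate 4 (0.0702) or control replicate 3 (0.0629), and Nfkbiz without any library but control replicate 5, up to 0.146 without myeloma replicate 4. Nfkbiz also lost it with the length and GC correction (0.0763), limma-voom (0.0602), robust dispersion (0.123) and the effective-length offset (0.0647), and Tnfaip3 with robust dispersion (0.0718). The median of this list was -0.03 while its mean was 0.01 and the test's direction higher, and it passed without control replicate 1 (0.0179) and with the replicate number as a block (0.00437). Of 50 cell cycle genes Cenpa alone was called, lower at -0.69 (SE 0.11), also adjusted over the list alone (list adjusted p = 0.592, median 0.03, test's direction lower). Without myeloma replicate 5 the cell cycle list passed, with 7 genes lower, a median of -0.42 and adjusted p = 9.08e-05.

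Glycolysis and hypoxia genes were higher for 5 of 28 and lower for 1, with 8 and 2 adjusted over the list alone (adjusted p = 0.0647), and the list passed without myeloma replicate 4 (0.0375), with limma-voom (0.0258), with the effective-length offset (0.0476) and with no filter (0.0173). The 5 were Pgam1 (log2 fold change 0.54), Slc16a3 (1.16), Mif (0.45), Ldha (0.34) and Pfkp (0.29), the last chosen after its value was seen, and Pdk1 (-0.41) was lower. None of these 6 passed without control replicate 3, where adjusted p ran from 0.0563 for Mif to 0.195 for Pfkp. For MYC and ribosome biogenesis 3 of 30 were higher, Ran (0.41), Hspe1 and Ldha, and Nop56 (-0.36) lower, with 4 and 1 adjusted over the list alone (adjusted p = 0.174). None of these 4 passed without myeloma replicate 4, at 0.0782 for Ran, 0.129 for Ldha and 0.138 for Hspe1 and Nop56. In the TGF-beta response 3 of 16 were higher, Pmepa1 (0.94), Itgae (0.71) and Skil (0.49), and Smurf1 (-0.44) and Tgfbr2 (-0.37) lower, with 3 and 2 adjusted over the list alone (adjusted p = 0.299). Pmepa1 passed whichever library was left out, while without myeloma replicate 4 Itgae (0.0556), Skil (0.0866), Smurf1 (0.0638) and Tgfbr2 (0.0519) did not. With the length and GC correction this list passed (0.0228). In death receptor, apoptosis and p53 genes Casp8 (0.38) and Bak1 (0.47) were higher and Bcl2 (-0.83) and Bcl2l11 (-0.40) lower of 23, with 4 and 2 adjusted over the list alone (adjusted p = 0.99). In IL-2 and gamma-chain signalling Socs1 (1.58), Jak3 (0.53) and Socs3 were higher and Bcl2, Il4ra (-0.41) and Il6ra (-0.52) lower of 24, with 8 and 5 adjusted over the list alone (adjusted p = 0.826). None of these 9 genes passed without control replicate 3, at 0.0828 for Casp8, 0.141 for Bak1, 0.0716 for Bcl2, 0.166 for Bcl2l11, 0.0635 for Socs1, 0.0795 for Jak3, 0.0911 for Socs3, 0.116 for Il4ra and 0.153 for Il6ra. All the genes named here except Pmepa1 and Itgae also lost their calls without at least 1 other library. With the length and GC correction Pgam1 (0.086), Ldha (0.338), Ran (0.0851), Hspe1 (0.358), Nop56 (0.06), Smurf1 (0.0815), Tgfbr2 (0.225), Casp8 (0.0836), Bak1 (0.0879), Bcl2 (0.0565), Bcl2l11 (0.149), Socs3 (0.138), Il4ra (0.181) and Il6ra (0.231) lost their calls, and Mif turned to -0.03. Pfkp lost its call with 9 other settings on all 6 libraries, from limma-voom (0.0508) to the replicate number as a block (0.184). With the effective-length offset Slc16a3 (0.103), Skil (0.0553), Ran (0.159), Nop56 (0.194), Ldha (0.0857), Hspe1 (0.0621), Bak1 (0.0801), Socs3 (0.0554) and Il4ra (0.0546) lost theirs, and Socs1 (0.0918) did with robust dispersion. Skil, Il4ra and Il6ra were chosen after their values were seen.

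**Figure D3:**
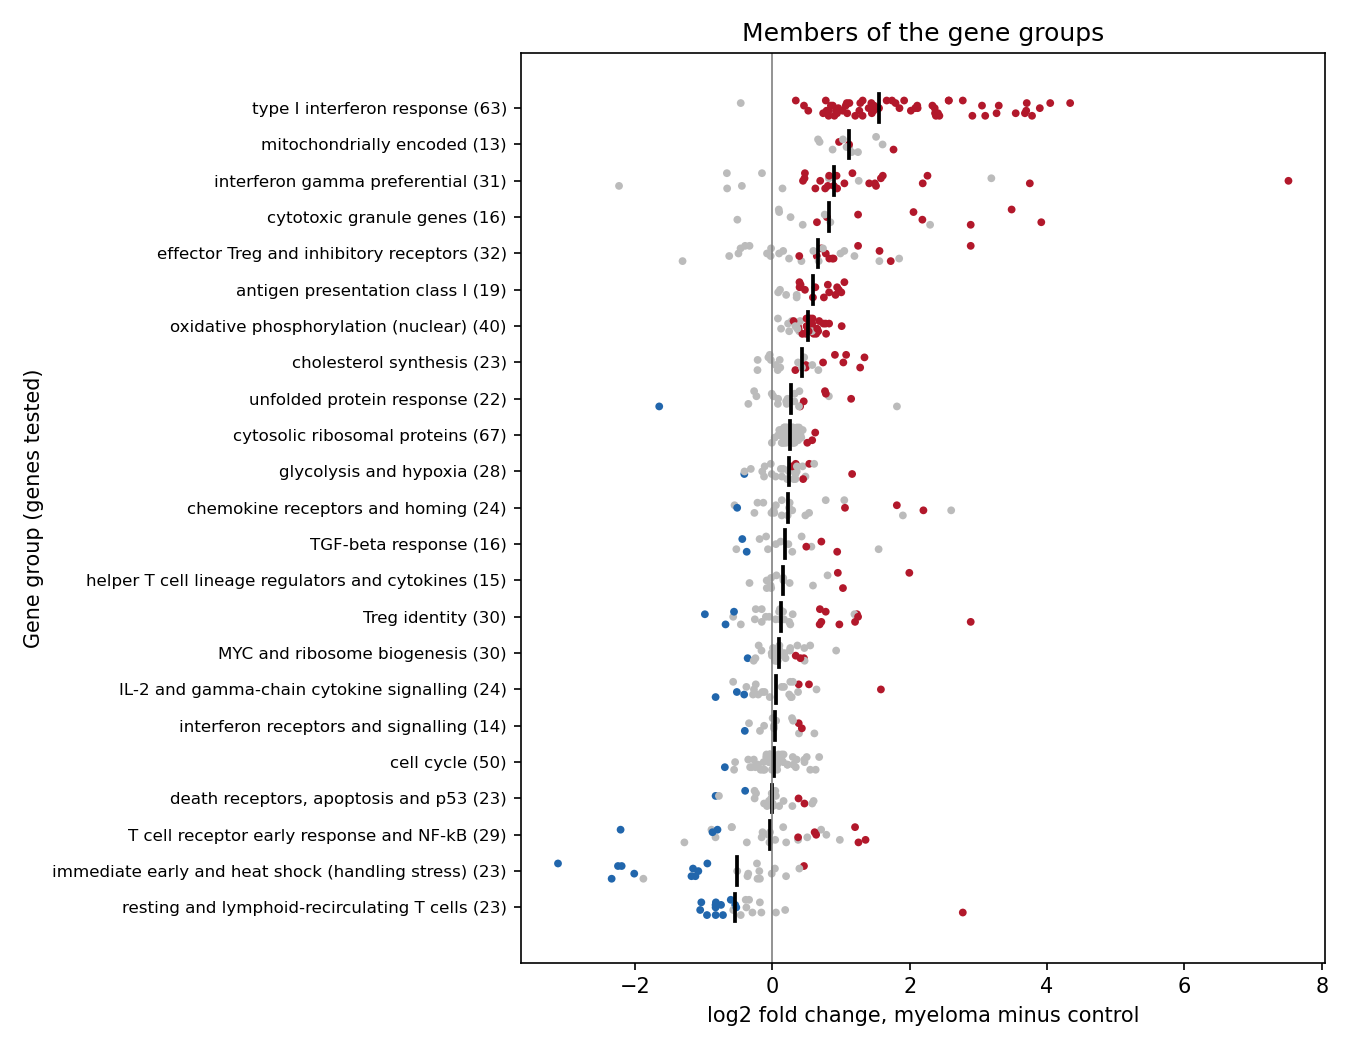
Each point is the log2 fold change (myeloma minus control) of 1 member of a gene group, red where it rose and blue where it fell at an adjusted p under 0.05 and grey otherwise, and the black bar is the group's median. The type I interferon group has the highest median, 1.55, and resting T cell genes the lowest, -0.54.

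Markers of other marrow cells were measured beside the sorted population. Of 16 B cell markers 5 fell and none rose, with 10 lower adjusted over the list alone and a median of -2.11. The complement receptor Cr2 (log2 fold change -4.47, SE 0.75), Fcer2a (-3.86, SE 0.96), Pax5 and Cd22 (-1.95, SE 0.52), the last chosen after its value was seen, were among them. Of 17 plasma cell markers 6 rose (8 adjusted over the list alone), with a median of 1.41. The immunoglobulin heavy chain gene Ighg2b went from 2.62 ± 3.69 to 804 ± 788 CPM (log2 fold change 8.25, SE 1.32, adjusted p = 0.00708), and Jchain from 2.66 ± 1.78 to 119 ± 80.8 CPM. Igkc and Fkbp11 were also higher, at 3.33 (SE 0.68) and 2.94 (SE 0.58). Fkbp11 was low, at a mean of 2.30 CPM in myeloma and 0.289 CPM in controls. The B cell list gave adjusted p = 1.13e-05, and adjusted p = 0.452 with an estimated correlation. The plasma cell list gave adjusted p = 0.000184, and adjusted p = 0.366 with an estimated correlation. B cell markers called numbered 1 without myeloma replicate 3, myeloma replicate 4, control replicate 3 or control replicate 5, and 11 without control replicate 1. Plasma cell markers called numbered 2 without myeloma replicate 4 or control replicate 3 and 3 without control replicate 1 or 5. Pax5 (0.0754, 0.105, 0.091, 0.0932), Fcer2a (0.0918, 0.129, 0.1, 0.131) and Cd22 (0.127, 0.141, 0.14, 0.15) lost their calls without myeloma replicate 3, myeloma replicate 4, control replicate 3 or control replicate 5. With limma-voom 3 plasma cell and 1 B cell markers were called, and Ighg2b (0.281), Jchain (0.0797), Pax5 (0.151), Fcer2a (0.208) and Cd22 (0.19) lost their calls. With robust dispersion 2 and 1 were called, and Ighg2b (0.0727), Igkc (0.114), Pax5 (0.119), Fcer2a (0.0883) and Cd22 (0.117) lost theirs. Cd22 also lost its call with the length and GC correction (0.0594), under which 4 plasma cell markers were called. Igkc (0.0569, 0.0513, 0.0749, 0.0565) and Fkbp11 (0.0638, 0.0535, 0.0751, 0.0698) lost theirs without myeloma replicate 4, control replicate 1, control replicate 3 or control replicate 5.

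**Figure D4:**
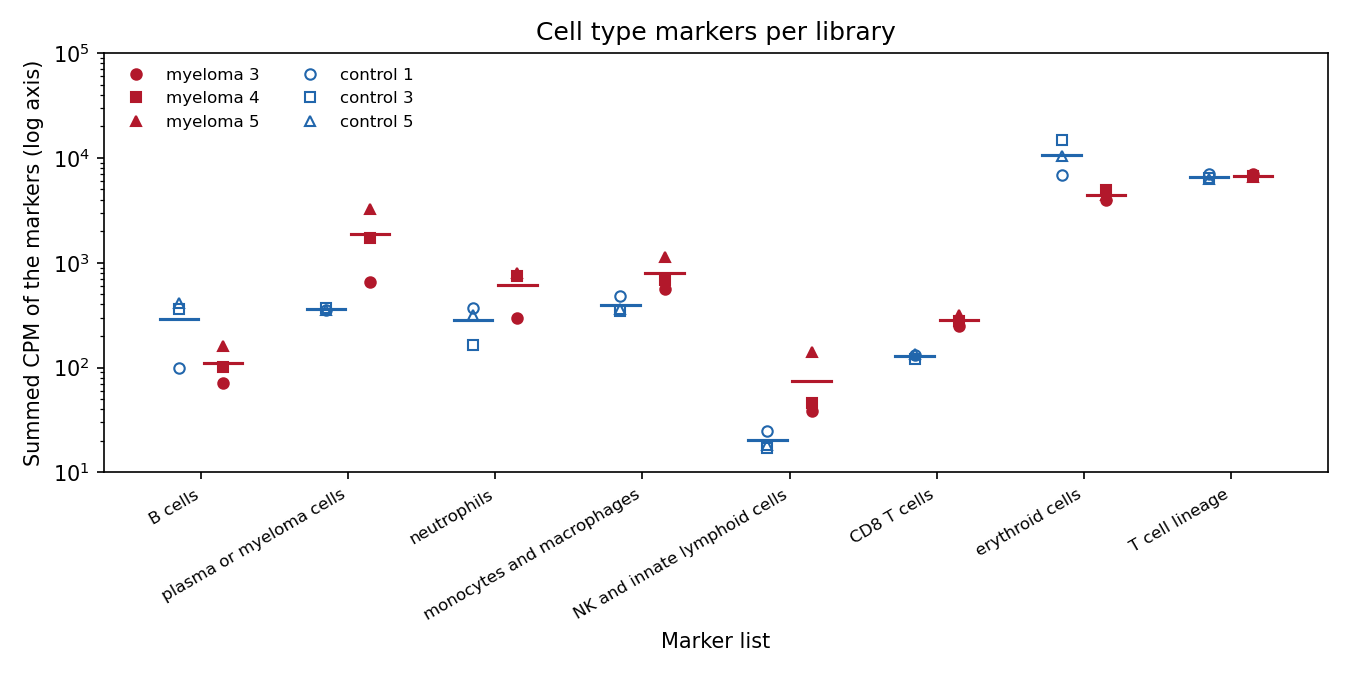
Summed CPM of the markers of 8 cell types per library on a log axis, with filled points for myeloma, open points for controls and a line at each group's mean. Plasma cell markers sum to 650 to 3254 CPM in myeloma and 355 to 372 CPM in controls, and T cell markers to 6508 to 6994 and 6313 to 7049 CPM.

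Among erythroid markers, the haemoglobin genes Hba-a1 (log2 fold change -1.39, SE 0.20), Hba-a2 (-1.29), Hbb-bt (-1.26) and Hbb-bs (-1.34, chosen after its value was seen) and the haem synthesis gene Alas2 (-1.65) were the 5 of 16 that fell (5 lower and 1 higher adjusted over the list alone). The list's median was 0.17 and its mean -0.09, while the test gave a lower direction (adjusted p = 0.0233, and adjusted p = 0.548 with an estimated correlation). Hba-a1 and Hba-a2 are near-identical copies. Haemoglobin transcripts took 0.69%, 1.45% and 1.06% of counts in control replicates 1, 3 and 5, against 0.374%, 0.465% and 0.388% in myeloma replicates 3, 4 and 5. The erythroid list lost its call without myeloma replicate 3 (0.376) or 4 (0.107), where 2 markers were lower. It also lost its call with DESeq2 (0.171), with limma-voom (0.0985) and with immunoglobulin, haemoglobin and mitochondrial genes left out (0.991), where 1 of 12 markers was lower and the median was 0.37. Its median turned to -0.05 without control replicate 5 and -0.47 without myeloma replicate 5. Alas2 lost its call without myeloma replicate 4 (0.0531), Hba-a2 without myeloma replicate 3 (0.056), Hbb-bt without myeloma replicate 3 (0.0548) or 4 (0.0567), and Hbb-bs without myeloma replicate 3 (0.0631) or 4 (0.0545). With robust dispersion Alas2 (0.0522) and Hbb-bs (0.0506) lost theirs.

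Monocyte and macrophage markers had 4 of 19 higher (7 adjusted over the list alone, median 1.81), of which Ctss, a lysosomal protease, rose 2.05-fold, the complement gene C1qa 5.40-fold, Ms4a7 10.5-fold and the Fc receptor gene Fcgr1 10.7-fold. Levels of the last 2 were low. Fcgr1 was at 1.27, 1.89 and 11.2 CPM in myeloma replicates 3, 4 and 5 and 0.258 to 0.726 CPM in controls. Ms4a7 was at 1.69, 2.68 and 9.20 CPM and 0.0726 to 0.858 CPM. The list gave adjusted p = 8.18e-05, and adjusted p = 0.463 with an estimated correlation. Without myeloma replicate 5 the median was 0.47, 1 marker was called and C1qa was not (0.0817). C1qa also lost its call without myeloma replicate 4 (0.085), control replicate 3 (0.149) or control replicate 5 (0.147), and 1 marker was called without each of these libraries. Ms4a7 (0.0804, 0.114, 0.146, 0.119) and Fcgr1 (0.0685, 0.15, 0.155, 0.0944) lost theirs without myeloma replicate 4, myeloma replicate 5, control replicate 3 or control replicate 5, and Fcgr1 also without control replicate 1 (0.113). With limma-voom Ms4a7 (0.0961), C1qa (0.143) and Fcgr1 (0.169) lost theirs, as they did with the length and GC correction (0.0545, 0.0854, 0.0634). C1qa did with robust dispersion (0.169), and C1qa (0.0563) and Fcgr1 (0.211) with the effective-length offset. Without myeloma replicate 3, 7 markers were called. Neutrophil markers had 2 of 20 higher, Pglyrp1 and Prtn3 (8 adjusted over the list alone, median 1.25). The neutrophil list gave adjusted p = 0.000173, and adjusted p = 0.463 with an estimated correlation. Without myeloma replicate 3, 7 neutrophil markers were called, and 1 without myeloma replicate 4, control replicate 1 or control replicate 3. Prtn3 passed only without myeloma replicate 5 among the fits that left out 1 library, with adjusted p from 0.0662 without control replicate 1 to 0.178 without control replicate 3. It also lost its call with 8 other settings on all 6 libraries, from RLE factors (0.0505) to the replicate number as a block (0.195). For NK and innate lymphoid markers 2 of 6 rose, Nkg7 at 4.16-fold and Gzma at 11.2-fold (3 adjusted over the list alone), and 4 of the 6 are held by another list. Gzma was low, at a mean of 2.96 CPM in myeloma and 0.248 CPM in controls. The median of the 6 was 1.95, and 0.62 without myeloma replicate 5. The NK list gave adjusted p = 0.0126, and adjusted p = 0.366 with an estimated correlation, and it lost its call without control replicate 1 (0.0621) or 5 (0.0772) and with no filter (0.181). Gzma kept its call only without control replicate 5, with adjusted p from 0.061 without myeloma replicate 4 to 0.114 without control replicate 3, and lost it with the length and GC correction (0.0547).

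Of 7 CD8 T cell markers, Ccl5 and Nkg7 rose (2 adjusted over the list alone), while Cd8a (log2 fold change 0.80, adjusted p = 0.415) and Cd8b1 (0.45, adjusted p = 0.146) were not called. The CD8 list gave adjusted p = 0.00119, and adjusted p = 0.286 with an estimated correlation. The only stem and progenitor marker of 9 called was Ly6a (4.32-fold), an interferon-inducible gene of T cells (2 adjusted over the list alone). The stem cell list's median was 0.82, and 0.33 without myeloma replicate 5, 0.45 without myeloma replicate 4 and 0.49 without control replicate 3. That list gave adjusted p = 0.00267, and adjusted p = 0.261 with an estimated correlation. The only dendritic cell marker of 11 called was Bst2 (1 adjusted over the list alone). The dendritic list gave adjusted p = 0.0173, and adjusted p = 0.397 with an estimated correlation, and it lost its call without myeloma replicate 5 (0.11) or control replicate 1 (0.143), with limma-voom (0.338), with no filter (0.0614) and with the replicate number as a block (0.146). Its median of 0.15 turned to -0.11 without myeloma replicate 4. Markers of the T cell lineage (1 of 16 higher, Cd3g at 0.37, adjusted p = 0.99), conventional CD4 T cells (Tbx21 higher and Tnfsf8, at -0.79, lower of 7, 0.355) and stromal and endothelial cells (Pecam1, at -0.52, lower of 6, 0.76) were not called as lists. Without control replicate 3, Cd3g (0.111) and Tnfsf8 (0.0789) lost their calls, as they did without myeloma replicate 3 (0.136, 0.0729), control replicate 1 (0.0627, 0.0732) or control replicate 5 (0.137, 0.0542), and Cd3g also without myeloma replicate 4 (0.126), with the length and GC correction (0.101), the effective-length offset (0.0669), library sizes alone (0.0902) and upper-quartile factors (0.0512). The median of the T cell lineage list was just under 0 and its mean 0.02. Adjusted over the list alone these lists gave 2 higher and 1 lower, 2 higher and 1 lower, and 0 higher and 1 lower. Only 4 megakaryocyte genes and 4 mast cell, basophil or eosinophil genes were measured, too few for the list test. None of the former was called, and of the latter Ccr3 rose 2.59-fold, a call lost without control replicate 3 (0.0767) or 5 (0.0662).

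The first principal component held 40.8% of the variance of log2 CPM and separated the groups, with myeloma libraries at -25.8 to -44.9 and controls at 21.9 to 42.4. The second held 23.4% and set myeloma replicate 5 apart at -46.7, against 37.5 and 19.1 for myeloma replicates 3 and 4. No 2 libraries agreed within sampling noise, the closest pair of a group being myeloma replicates 3 and 4 with a chi-square per degree of freedom of 8.63.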

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

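The length and GC correction was chosen after the data were examined. Main counts were 838 genes higher and 621 lower. Lower genes numbered 1004 with library sizes alone (633 higher), 405 with the effective-length offset and 964 with DESeq2. Without a filter 26583 genes were tested, with 1337 higher and 1102 lower. In that fit the p-values of Lag3, Tigit and Pdcd1 did not reflect the spread between libraries, so its larger counts are not taken as more evidence. The length and GC correction gave 453 and 299. Without 1 library, 331 to 836 genes were higher and 123 to 546 lower, from fits with fewer samples, and the fewest came without control replicate 3. Otherwise the cause was not tested. Apart from the replicate block, whose counts follow below, the other settings stayed within 1.5 times the main counts. Replicate numbers 3 and 5 occur in both groups, but same-numbered libraries deviated together little (correlations 0.0295 and 0.0974), so the numbers were not taken as pairs. The replicate block gave 362 higher and 142 lower. In that fit myeloma replicate 4 and control replicate 1 have no partner and add nothing to the group contrast. Few residual degrees of freedom are left, so calls lost there do not by themselves show that a result is fragile. Type I interferon members higher ranged from 56 to 60 without 1 library.

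With an estimated correlation the type I interferon list, median 1.55, had adjusted p = 0.0673, and all 23 called lists lost their call. With fry 13 lists lost it and 1 gained it. Fry kept the type I interferon, interferon gamma and class I lists (adjusted p = 0.00436 each) and the resting T cell list (adjusted p = 0.0128), among others. It does not compare a list with other genes. Robust dispersion leaves camera's p-values as they were, while members called numbered 4 lower for immediate early genes, 0 for mitochondrial genes, 1 lower for B cell markers and 2 higher for plasma cell markers. The replicate block left 2 oxidative phosphorylation genes called. In every other setting at least 20 of the 23 lists stayed called. Calls of single genes were lost for 39 genes with the length and GC correction, 56 in the block fit, 27 with robust dispersion, 25 with the effective-length offset, 21 with limma-voom, 8 with library sizes alone and 1 to 3 in each other setting on all 6 libraries.

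Signs turned for uncalled genes: Ikzf2 (-0.025), Ifnar2 (-0.052) and Cd3e (-0.030) with library sizes alone, Ikzf2 (-0.0020) with the effective-length offset, Ctla4 (0.18) and Ifnar2 (-0.021) in the block fit, and Ifnar2 (-0.019) and Cd3e (-0.069) with the length and GC correction, which also turned Mif (-0.028), a called gene. Without 1 library the log2 fold change ranged from -0.075 to 0.13 for Ifnar2, -0.54 to 0.032 for Ctla4, -0.053 to 0.15 for Ikzf2, -0.0085 to 0.11 for Cd3e and -0.42 to 0.032 for Itgb3.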

Other observations

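Tests of the interferon genes, of the plasma and B cell markers and of immunoglobulin segments were chosen after the results were seen. Tests of the oxidative phosphorylation and resting T cell lists had predictions written before their results, as did the count of other splits, but the length and GC correction behind the list tests was itself chosen after the data were examined. Immunoglobulin variable segments were counted per library. Of kappa variable reads in myeloma replicates 3, 4 and 5, Igkv1-110 took 64.5% (60.6 to 68.2, of 622 reads), 93.2% (92.1 to 94.2, of 2175) and 92.9% (92.1 to 93.6, of 4674), against 12.6%, 4.55% and 2.35% in control replicates 1, 3 and 5. The heavy segment Ighv1-82 took 18.0% (14.2 to 22.4, of 361), 83.1% (80.3 to 85.6, of 810) and 93.8% (92.6 to 94.8, of 1895) in myeloma, against 10.4%, 1.35% and 3.09%. In myeloma replicate 3 the leading heavy segment was Ighv7-3, with 49.9% (44.6 to 55.1). Intervals are exact binomial.

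Of 63 type I interferon genes 62 were higher in myeloma. RNA from plasma or myeloid cells would bring their excess up with the markers. Myeloma replicates 3 and 5 were compared because they had the lowest and highest marker levels in myeloma. A low marker ratio was thus set by that choice. For each gene, the excess over the control mean in replicate 3 was divided by that in replicate 5. The median of these ratios was, however, 0.951 for the 62 interferon members (quartiles 0.797 to 1.04). For 10 plasma and myeloid markers it was 0.111 (0.0592 to 0.392). Igha (3.06) and Ctss (0.852) did not follow the other 8, and a source that goes with those stays open. Myeloma replicate 4 and the neutrophil and NK markers did not enter this comparison. After the length and GC correction the list's median was 1.52 (SE 0.19) with 61 members higher, which argues against that trend as the whole cause. A response of the sorted cells to interferon in myeloma-bearing marrow may account for the pattern, as a hypothesis found and examined on the same data. Reads shared among paralogs, an unrecorded batch that follows the groups and the source of any interferon were not tested.

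By edgeR 6 of 17 plasma cell markers were higher and 5 of 16 B cell markers lower, 2 and 1 with robust dispersion, and the lists had adjusted p = 0.366 and adjusted p = 0.452 with an estimated correlation. One lower share of the sorted type would raise both, but the medians were -2.11 (SE 0.38) for B cells and 1.41 (SE 0.931) for plasma cells. These SEs come from resampling the genes of each list, not the libraries. Summed B cell markers in control replicate 1 (99.5 CPM) lay within the myeloma range of 70.85 to 159 CPM. The B cell difference thus lay with control replicates 3 and 5 (360 and 415 CPM). In myeloma replicate 3 Ighv1-82 held 18.0%, behind Ighv7-3 (49.9%) and Ighv1-81 (27.4%), which argues against 1 clone as the whole source in all 3 libraries, but Igkv1-110 led its kappa reads too (64.5%, ahead of Igkv1-117 at 31.2%), so the same clone as part of replicate 3 stays open. For myeloma replicates 4 and 5, transcripts of 1 plasma cell clone may be present, since a shared kappa and a shared heavy segment held at least 83.1% of their reads. How these transcripts entered a CD4+ GFP+ sort, as cells or as free RNA, stays open.

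Log2 fold change and transcript length had a Spearman correlation of -0.326 across genes, which are not independent replicates. After the length and GC correction the resting T cell list had a median of -0.59 (SE 0.11) with 12 genes lower, which argues against the trend as its whole cause. For oxidative phosphorylation the corrected median was 0.281 (SE 0.044), from 0.52, with 6 genes called in place of 28. Camera at the preset correlation gave the list adjusted p = 2.86e-07 after correction, weaker than the adjusted p = 1.61e-16 before it. With an estimated correlation the uncorrected list had adjusted p = 0.261. Of 10000 random lists matched on length and expression, but not on GC content, 100% had a median below the uncorrected 0.52 (median 0.298, 0.2 to 0.412). Genes of the random lists were drawn independently, while those of the real list move together (estimated correlation 0.321). Their spread is therefore too narrow for this share to decide whether length alone is the whole cause. The corrected median met the bound written beforehand and the list kept its call. It exceeded that bound by less than its SE, a margin that the prediction did not ask for. How much of the rise goes with the trend and how much is a change in these genes is left open here for want of that margin.

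Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many genes, with 838 higher, 621 lower and 62 interferon members. The highest of the other splits was 0 for each by edgeR, with 149 to 713 genes at an unadjusted p under 0.05 against 3698. Each other split mixes the real groups, so any difference between them widens the spread within its groups and removes calls. Few calls there could be foreseen, and these splits are no measure of chance. With 10 splits the share is never under 0.1.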
